A study of Homo sapiens with 6 samples.

How the data were processed

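Gene expression was measured on 6 Affymetrix oligonucleotide arrays hybridised with RNA of PC3 cells, a human prostate cancer cell line established from a bone metastasis. Per the labels' protocols, cells were transfected either with an empty vector or with a plasmid carrying prostate-specific membrane antigen (PSMA, the product of FOLH1) and then selected with puromycin. The transfection used 3 µg of plasmid with 2 µg of FuGENE 6 for 30 min, with 72 h of recovery before selection. Biotin-labelled cRNA was made from 2 µg of total RNA, per the labels' protocols. The labels placed 3 arrays in a control group (replicates 1 to 3) and 3 in a PSMA group (replicates 4 to 6). Titles and genotype labels called the control cells wild type, while their source label named the vector alone, so it stays open whether they carried the empty vector.

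The deposited values were processed intensities, 1 per probe set and array, made with GCRMA per the submitters' processing notes. GCRMA corrects background by probe base composition, normalizes across arrays and summarises the probes of a set. Its version and any later step were not given in the sources used here. The scale was not stated either. Values ran from 3.76 to 17455, with a median of 51.7 to 52.9 on each array, and were therefore taken as linear intensities in arbitrary units. GCRMA pulls dim probe sets towards a common low value, so a fold against a group at that level depends on the background correction. For arrays, precision is limited by their number, here 3 in each group.

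The table held 22277 probe sets. Of these, 62 were control probe sets, 19064 had 1 gene symbol in the annotation used, 1043 had several and 2108 were unnamed here. Symbols were checked through gene identifiers against the RefSeq table of assembly GRCh38.p14, in which 19058 of the single-gene probe sets were found, and 0 needed an update. No gene was named from a probe set with several symbols, except that the FOLH1 probe sets shared with its near-identical paralog FOLH1B were reported as such.

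The values were log2-transformed here with no pseudocount and no further normalization. Control probe sets were left out, as were probe sets not above the median of all values (52.5) on at least 3 of the 6 arrays, which left 11303 probe sets (50.9%). Each of 7035 genes was represented by the single-gene probe set with the highest mean log2 value over all 6 arrays. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings) as arrays labelled PSMA minus arrays labelled control. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. All adjusted p-values of single genes are from limma. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for summaries and plots. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

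Gene lists were tested with camera (limma, preset inter-gene correlation of 0.01), adjusted over the 22 lists with at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, one way and does not compare the list with other genes. For each list, the number of changed members was also computed with p-values adjusted over the list alone. The 26 lists covered folate and one-carbon enzymes, glutamate signalling, glutamate metabolism, the PI3K, AKT and mTOR pathway, targets of ERK signalling, androgen receptor and luminal genes, cell cycle, CDK inhibitors and p53 targets, epithelial junctions, mesenchymal genes, integrins and adhesion, extracellular matrix, angiogenesis, NF-kB targets and cytokines, interferon-stimulated genes, antigen presentation, the unfolded protein response, hypoxia and glycolysis, sterol and lipid synthesis, xenobiotic and antioxidant genes, growth factor receptors, neuroendocrine markers, cancer-testis antigens, leucocyte markers, fibroblast and endothelial markers, and reference genes.

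The groups, the tests, the filter, the lists, the rule for named genes and the alternatives were set before the data were examined, unless said otherwise. The rule named FOLH1, the 10 genes with the largest increase and the 10 with the largest decrease among genes past the threshold whose groups did not overlap, and in each list the 2 members with the largest increase and the 2 with the largest decrease past the threshold. Where a list had no such member, its brightest member was named. Genes on the Y chromosome, XIST, and genes without a proper symbol were passed over. Any other gene named, including members named to complete a small count, was chosen after its values were seen.

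The order of genes along chromosomes was examined only after the results were seen. The 7033 tested genes with a place in the RefSeq table were put in reference order, log2 differences were limited to ±2, and means over windows of 15 consecutive tested genes were compared with 10000 shuffled orders. Overlapping windows beyond the level that the most extreme window reached in 5% of shuffled orders (0.585) were joined into stretches. The array's own genome build was not used, so no coordinates are given.

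The methods were tested on simulated data made from the real means and spreads of the 7035 genes. Of 50 genes changed at each size, 54% were recovered at a log2 change of 0.25, 92% at 0.5, 100% at 1 and 100% at 2. Of 186 calls, 13 (6.99%) were false. The other 6835 genes were left unchanged, whereas 63.6% of genes passed in the real data. The adjustment was therefore stricter in the simulation, and these rates do not carry over to the real calls. With no effect simulated, camera called 0 of 22 lists, and it called the 1 list shifted by 0.4. Genes were simulated as independent of each other, so this does not test list calls among correlated genes. In the gene-order test, 1 of 20 shuffled orders held a false stretch. Of 40 planted stretches of 30 genes shifted by 0.6 on the log2 scale, 35 were found. Most stretches found in the real order held fewer genes, and detection at their size was not tested. Alternatives covered the filter, the scaling between arrays, the variance model, array weights, the choice of probe set, the set test, a minimum fold, a floor on low values and leaving out each array. A covariate from the poly-A spike-in controls, the removal of genes in shifted stretches and, for single genes and FOLH1, the floor on low values and the minimum fold were added after seeing the data.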

Results

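By its labels, the series compared PC3 cells called wild type or vector alone with PC3 cells said to be transfected to express PSMA. The question was which transcripts differ between them. Arrays of the same group correlated at r = 0.9966 to 0.9983 across probe sets (6 pairs), and arrays of different groups at r = 0.9616 to 0.9630 (9 pairs); these correlations are across probe sets, which are not independent replicates. The first principal component held 91.8% of the variance and separated the 2 groups. The 3'/5' ratio of GAPDH was 1.30 ± 0.0668 (SD, n = 3) on arrays labelled control and 1.36 ± 0.0872 on arrays labelled PSMA, and that of ACTB was 4.61 ± 0.658 and 4.44 ± 0.757. The control probe set for the middle of 28S rRNA read 1498 ± 63.1 on arrays labelled control and 675 ± 4.29 on arrays labelled PSMA. The gap was smaller on the probe set for its 5' end, which read 5778 ± 681 and 4047 ± 358.

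Signal on the probe sets of FOLH1, the gene that encodes PSMA, a cell-surface carboxypeptidase that releases glutamate from folates and neuropeptides, was higher on the arrays labelled control than on those labelled PSMA. This is the opposite of what the labels state. The brightest of its probe sets, annotated to both FOLH1 and its paralog FOLH1B, read 480.8 ± 65.3 (SD, n = 3) on arrays labelled control and 12.5 ± 3.44 on arrays labelled PSMA, a 39.4-fold difference (log2 difference -5.30, SE 0.197, limma adjusted p = 2.6e-07). Its mean lay at percentile 83.6 of all probe sets in the first group and at percentile 23 in the second. The other 2 probe sets shared by both genes were 26.4-fold and 17-fold lower on arrays labelled PSMA. With values under the 25th percentile of the table (13) raised to it, which was chosen after seeing the data, the shared probe sets were 34.3-fold, 16.2-fold and 12.3-fold lower. The probe set annotated to FOLH1 alone read 60.5 ± 0.914 (percentile 52.3) and 28.1 ± 3.80 (percentile 40.5), a log2 difference of -1.11 (limma adjusted p = 1.5e-05), and the one annotated to FOLH1B alone read 57.1 ± 8.0 and 13.8 ± 1.29 (log2 difference -2.04).

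On all 5 probe sets, each array labelled control lay above each array labelled PSMA. The 3 shared probe sets cannot separate FOLH1 from FOLH1B, and the position of the 5 probe sets relative to the cloned sequence was not examined here. Because the signal on these probe sets goes against the labels, every direction given for a gene or list follows the labels as deposited. The words "higher" or "rose" mean higher on the arrays labelled PSMA, where the FOLH1 signal was lower.

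**Figure D1:**
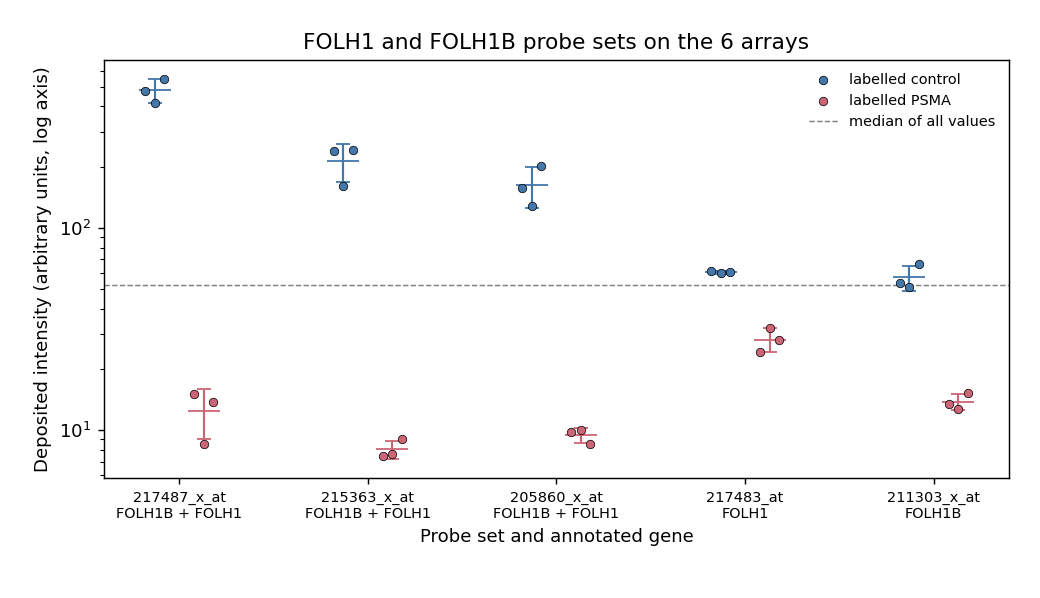
Deposited intensity (arbitrary units, log axis) of the 5 probe sets annotated to FOLH1, FOLH1B or both, with 1 point per array, horizontal bars at the mean and error bars of 1 SD (n = 3 per group). On each probe set the 3 arrays labelled control lie above the 3 labelled PSMA, and the dashed line marks the median of all values, 52.5.

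Among the 10 genes with the largest increase, DNAJC15, which encodes a mitochondrial co-chaperone, went from 14.2 ± 1.02 (SD, n = 3) on arrays labelled control to 702 ± 33.1 on arrays labelled PSMA. EPB41L3, which encodes a protein that links the membrane to the cytoskeleton, went from 7.31 ± 0.893 to 249.8 ± 36.6. These were 49.5-fold and 34.1-fold increases (limma adjusted p = 5.5e-10 and 1.5e-08), each against a group near background. With values under the 25th percentile raised to it, EPB41L3 was 19.0-fold higher and DNAJC15 did not change. The other 8 rose 5.38-fold to 9.08-fold. They were NAP1L3, a member of the nucleosome assembly family; ESM1, a secreted proteoglycan; SIGLEC15, a sialic acid-binding receptor; HSD17B2, which oxidises oestradiol and testosterone; BEX4; GBX2, a homeobox transcription factor; KCTD12; and GPALPP1. With the same floor, HSD17B2 was 6.15-fold rather than 6.80-fold higher. DNAJC15, ESM1, SIGLEC15, GBX2, KCTD12 and GPALPP1 lay among neighbouring genes that shifted the same way.

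The largest decrease was in VGLL1, a cofactor of TEAD transcription factors, which went from 377.7 ± 50.9 (SD, n = 3) on arrays labelled control to 5.86 ± 1.17 on arrays labelled PSMA, 65.0-fold lower and near background (limma adjusted p = 1.7e-08). ST6GALNAC5, a sialyltransferase, was 31.3-fold lower and PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, 16.3-fold lower. CXCR4, the receptor of the chemokine CXCL12, went from 144 ± 9.59 to 12.7 ± 0.621. IGFBP2, an insulin-like growth factor binding protein, went from 594 ± 31.5 to 87.4 ± 11. The heparan sulphate sulphotransferase HS3ST3A1, the interleukin 1 decoy receptor IL1R2, the phosphatase PTPN20, the small GTPase ARL14 and FRY fell 7.76-fold to 15.8-fold, and HS3ST3A1 and FRY lay among neighbouring genes that fell. With values under the 25th percentile raised to it, the decreases were 28.8-fold for VGLL1, 15.9-fold for ST6GALNAC5, 9.0-fold for PTGS2, 11-fold for CXCR4, 9.79-fold for HS3ST3A1, 7.29-fold for PTPN20 and 6.09-fold for FRY. FOLH1, by its single-gene probe set, fell by 1.11 on the log2 scale over the same arrays.

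Across all genes, 4476 of 7035 (63.6%) passed the limma threshold, 2118 higher and 2358 lower on arrays labelled PSMA. Most of these differences were small: the median size among changed genes was 0.34 on the log2 scale, and 310 genes differed by 2-fold or more, 133 higher and 177 lower. The 3 values of each group did not overlap in 4889 genes (69.5%), against 10% by chance. By probe set, 6846 of 11303 (60.6%) passed, 3188 higher and 3658 lower. With the test set against a minimum fold of 1.5, limma called 526 genes and 747 probe sets, and 62 of the 110 genes named by the rule. Counts of changed members in the lists below are to be read beside the 63.6% of all tested genes that passed.

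Genes of epithelial junctions fell on the arrays labelled PSMA, where the FOLH1 signal was lower. Of 25 tested members, 21 fell, 3 rose and 1, the keratin KRT19 (log2 difference -0.09), did not pass. The tight junction gene CLDN1 fell by 1.92 and the desmosomal plaque gene DSP, which went from 2004 ± 71.5 to 778.5 ± 23.8 (SD, n = 3), fell by 1.36 on the log2 scale. OCLN, another tight junction component, fell by 0.95, CLDN7 by 0.85, the epithelial splicing regulator ESRP1 by 0.79 and CDH1, which encodes E-cadherin, by 0.32. The 3 that rose were the transcription factor ELF3 (0.60), the desmosomal cadherin DSG2 (0.50), which lay in a raised stretch of chromosome 18, and TJP1 (0.18), whose probe sets disagreed in direction. The median log2 difference was -0.43, and 24 members passed when adjusted over the list alone. Camera called the list lower (limma, adjusted p = 0.000305), with adjusted p = 0.481 with an estimated correlation.

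Mesenchymal genes were mostly higher on the same arrays, with 14 of 21 tested members higher on arrays labelled PSMA, 3 lower and 4 not past the threshold (S100A4, CCN1, MMP9 and PLAUR, from -0.11 to 0.11). ZEB1, a transcriptional repressor of E-cadherin, rose from 41.8 ± 4.86 to 183 ± 15 (SD, n = 3), 4.39-fold. TGFBI, a secreted matrix protein induced by TGF-beta, rose 3.50-fold, and the transcription factor SNAI2 rose by 1.0 on the log2 scale. The intermediate filament gene VIM rose by 0.30 and CDH2, which encodes N-cadherin, by 0.26. The 3 that fell were fibronectin, FN1 (log2 difference -0.85), the collagenase MMP1 (-0.80) and TGFB1 (-0.23). The list's median was 0.37, with 17 members changed when adjusted over the list alone. Camera called it higher (limma, adjusted p = 0.00948), with adjusted p = 0.768 with an estimated correlation and 0.178 when dim probe sets were kept.

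Interferon-stimulated genes fell on arrays labelled PSMA, with 18 of 28 tested members lower, 9 of them by 2-fold or more. IRF9, the DNA-binding part of the complex that carries the type I interferon signal, went from 213 ± 15.4 to 56.0 ± 1.84 (SD, n = 3), 3.79-fold lower. IFI44L fell by 1.83, the antiviral GTPase MX1 by 1.74, GBP1 by 1.69, IFITM1 by 1.64 and IRF7 by 1.34 on the log2 scale. The 4 that rose were HERC5 (0.82), LGALS3BP (0.79), DDX60 (0.43) and SP110 (0.41), and 6 did not pass, among them IFIT2 (-0.04) and IFIT3 (0.01). Adjusted over the list alone, 24 members changed, 6 higher and 18 lower. The median was -0.37, and camera called the list lower (limma, adjusted p = 0.0141), with adjusted p = 0.768 with an estimated correlation. These directions, too, follow labels that the signal on the FOLH1 probe sets contradicts.

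**Figure D2:**
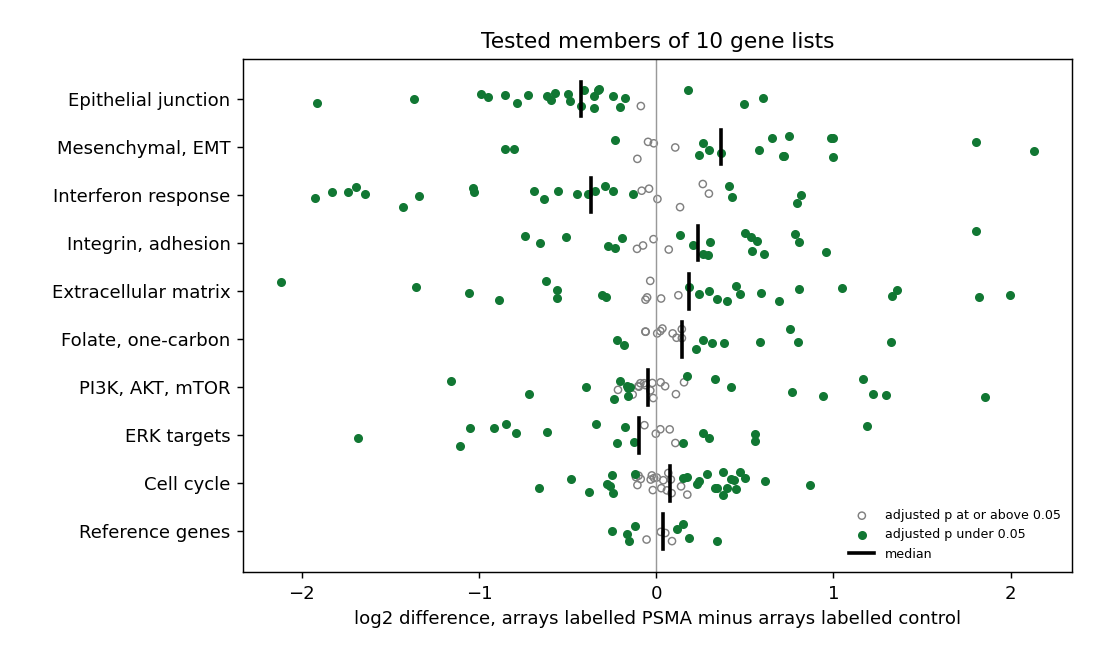
Log2 differences (arrays labelled PSMA minus arrays labelled control, n = 3 each) of the tested members of 10 gene lists, with 1 point per gene, filled where the adjusted p is under 0.05, and a black bar at each list's median. The epithelial (-0.43) and interferon (-0.37) medians lie below 0 and the mesenchymal median (0.37) above it; the FOLH1 signal was lower on the arrays labelled PSMA.

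Genes of antigen presentation went both ways, and the difference of this list from the interferon list was not tested. Of 19 tested members 6 rose, 5 fell and 8 did not pass, with 11 changed when adjusted over the list alone. The immunoproteasome subunit PSMB9 rose from 24.5 ± 3.27 on arrays labelled control to 84.6 ± 7.38 on arrays labelled PSMA (SD, n = 3), and the peptide transporter subunit TAP1 rose by 0.54 on the log2 scale. The 5 that fell were ULBP2 (-0.87), MICB (-0.71) and MICA (-0.46), ligands of an activating receptor of natural killer cells, with CALR (-0.35) and HLA-C (-0.14). Camera gave no call (limma, adjusted p = 0.964); its direction was up, the mean was 0.03, the median was -0.04 and fry's direction was down.

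Integrin and adhesion genes were mostly higher on arrays labelled PSMA. Of 24 tested members 14 rose, 6 fell and 4 (PTK2, FERMT1, ILK and ITGB1) did not pass. Adjusted over the list alone, 21 changed. FERMT2, which encodes an integrin activator, went from 610 ± 43.4 to 2133 ± 47.0 (SD, n = 3), and ITGB2 rose 1.94-fold. The integrin subunit ITGAV fell by 0.74 and PARVA, a focal adhesion adaptor, by 0.66 on the log2 scale, and ITGB1 had a log2 difference of -0.11 that did not pass. Among extracellular matrix genes 15 of 29 rose and 9 fell, with 24 changed when adjusted over the list alone. Collagen genes went both ways: COL6A3 rose 4.0-fold and COL4A1 3.54-fold, while COL4A6 fell 4.34-fold. The proteoglycan gene SDC2 fell 2.56-fold. FERMT2, COL6A3 and COL4A1 lay in raised stretches of neighbouring genes. Camera called neither list (limma, adjusted p = 0.142 and 0.269).

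PSMA acts on folates and on a glutamate-releasing neuropeptide, and its known biology led to lists for both substrates. MTHFD1, a cytosolic enzyme of one-carbon metabolism, rose from 1826 ± 9.76 on arrays labelled control to 4568 ± 77.9 on arrays labelled PSMA (SD, n = 3), and MTR, which encodes methionine synthase, rose 1.74-fold; MTHFD1 lay in a raised stretch of neighbouring genes and MTR in a lowered one. The folate carrier SLC19A1 fell by 0.22 and the mitochondrial enzyme MTHFD2 by 0.18 on the log2 scale. In all, 8 of 19 folate and one-carbon genes rose, 2 fell and 9 did not pass, with 10 changed when adjusted over the list alone (camera adjusted p = 0.104, limma). Of all tested genes, 63.6% passed. Of 17 genes of glutamate metabolism 5 rose (GLUL, SLC1A3, GOT2, GLUD1 and SLC38A2) and 8 fell, with 13 changed when adjusted over the list alone and no camera call (limma, adjusted p = 0.892). Glutamine synthetase, GLUL, in a raised stretch, rose by 0.95, while the cystine and glutamate exchanger SLC7A11 fell by 0.69 and asparagine synthetase, ASNS, by 0.53. Most glutamate receptor genes were below the filter; the 2 tested members of that list, the scaffold genes HOMER1 (-0.49) and HOMER3 (-0.21), both fell, also when adjusted over the list alone, and were too few for a list test.

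Components of the PI3K, AKT and mTOR pathway moved in both directions on the arrays labelled PSMA, with 9 of 32 higher, 9 lower and 14 not past the threshold. IRS2 and IRS1, adaptors of insulin and insulin-like growth factor receptors, rose 3.62-fold and 2.46-fold, IRS2 within a raised stretch. DDIT4, an inhibitor of mTOR complex 1, fell by 1.16 and PIK3C2A by 0.72 on the log2 scale, and the kinase gene AKT1 fell by 0.24. Adjusted over the list alone, 18 changed. The median was -0.05, whereas the mean was 0.14 and camera pointed up without a call (limma, adjusted p = 0.892). Of 22 immediate early and feedback genes of ERK signalling, 6 rose and 11 fell, with 17 changed when adjusted over the list alone and no call (limma, adjusted p = 0.510). The phosphatase gene DUSP5 rose 2.28-fold and SPRY4 1.47-fold, while ATF3 fell 3.21-fold and IER3 2.15-fold.

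Receptor and ligand genes of growth factors included EGFR, which rose from 297 ± 16.1 to 597 ± 35.6 (SD, n = 3) on arrays labelled PSMA within a raised stretch of chromosome 7, and its ligand EGF, which fell 2.19-fold. IGFBP4 rose by 0.93 and IGFBP2 fell by 2.77 on the log2 scale. Of the 21 tested members 8 rose and 8 fell, and 16 changed when adjusted over the list alone. The median was 0.05, whereas the mean was -0.16 and camera pointed down (limma, adjusted p = 0.964). Among angiogenesis genes 9 of 21 rose and 9 fell, with 18 changed when adjusted over the list alone (camera adjusted p = 0.892, limma). PDGFB rose by 0.49 and PDGFC by 0.45, while the protease gene ADAMTS1 fell by 1.61 and the vasoactive peptide gene ADM by 0.92. NF-kB targets and cytokines split in the same way, with 8 of 19 higher and 7 lower, 15 changed when adjusted over the list alone, and no call (limma, adjusted p = 0.964). The neutrophil chemokine genes CXCL6 and CXCL5 rose 2.27-fold and 2.10-fold, and IL1RN, the interleukin 1 receptor antagonist, fell 2.97-fold beside PTGS2.

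Cell cycle genes differed little in size between the groups. Of 42 tested members 17 rose, 8 fell and 17 did not pass, 0 reached 2-fold, and 25 changed when adjusted over the list alone (camera adjusted p = 0.204, limma). CCNE2, a cyclin of the G1 to S transition, rose by 0.87 and NUSAP1 by 0.61, while E2F8, in a lowered stretch, fell by 0.66 and FOXM1 by 0.48 on the log2 scale. The proliferation marker MKI67 had a log2 difference of -0.03 that did not pass. Among CDK inhibitors and p53 targets, GDF15, a secreted stress cytokine, went from 549 ± 44.2 on arrays labelled control to 81.8 ± 6.92 on arrays labelled PSMA (SD, n = 3), and CDKN1A, which encodes p21, fell 2.50-fold. In that list 4 of 15 rose (PLK2, in a raised stretch, by 0.68, GADD45B by 0.65, XPC by 0.60 and CDKN2A by 0.19) and 6 fell, with 10 changed when adjusted over the list alone. Camera gave no call (limma, adjusted p = 0.892).

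Genes of sterol and lipid synthesis were more often lower than higher on arrays labelled PSMA. Of 26 tested members 14 fell, 5 rose and 7 did not pass. Adjusted over the list alone, 19 changed (camera adjusted p = 0.204, limma). SREBF1, a master transcription factor of lipid synthesis, went from 335 ± 9.85 to 86.2 ± 5.35 (SD, n = 3) within the lowered stretch of chromosome 17, and INSIG1 fell by 0.97 on the log2 scale. The 5 that rose were HSD17B7 (0.51), FDPS (0.36), SREBF2 (0.24), SQLE (0.21) and MVK (0.16). Hypoxia and glycolysis genes had 7 of 32 higher and 14 lower, and 22 changed when adjusted over the list alone (camera adjusted p = 0.530, limma). CA12 (0.56) and ENO1 (0.36) rose, and MXI1 (-0.66) fell beside ADM. In the unfolded protein response 4 of 28 rose (ERO1A by 1.02, EDEM2 by 0.52, CRELD2 by 0.40 and DNAJC3 by 0.35) and 10 fell, among them the chaperone gene DNAJB9 (-0.82) and the stress transcription factor DDIT3 (-0.74); ERO1A and DNAJC3 lay in raised stretches. That list had 14 changed members when adjusted over the list alone and no call (limma, adjusted p = 0.530). Of 22 xenobiotic and antioxidant genes 8 rose and 10 fell, and 18 changed when adjusted over the list alone (camera adjusted p = 0.731, limma). CYP1B1 (0.62) and HMOX1 (0.39) rose, and GSTP1 (-0.74) fell beside SLC7A11.

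Androgen receptor targets and luminal genes went both ways on the arrays labelled PSMA. Of 12 tested members 5 rose (STEAP1 by 0.57, PLPP1 by 0.57, ABCC4 by 0.52, HOXB13 by 0.38 and PMEPA1 by 0.36), PLPP1 and ABCC4 within raised stretches, and 6 fell, led by NDRG1 (-0.99) and ELL2 (-0.74), with 11 changed when adjusted over the list alone (camera adjusted p = 0.892, limma). Of 5 neuroendocrine markers the transcription factor gene FOXA2 rose 2.67-fold, SYT1 (-0.56) and ENO2 (-0.27) fell, and 3 changed when adjusted over the list alone. Their mean was 0.10 and their median -0.10, with camera down (limma, adjusted p = 0.892) and fry up. Reference genes were near balance on the arrays of both labels, with 4 of 12 higher (SDHA, PPIA, TFRC and B2M), 4 lower (PGK1, GUSB, YWHAZ and GAPDH) and a range from -0.25 to 0.34; 8 changed when adjusted over the list alone (camera adjusted p = 0.892, limma).

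Markers of cells other than PC3 were mostly below the filter. Of the leucocyte markers 4 were tested; CORO1A rose from 36.0 ± 4.78 to 55.5 ± 3.62 (SD, n = 3) and SRGN by 0.16 on the log2 scale, while ARHGDIB (0.02) and HCLS1 (-0.10) did not pass. Of 3 tested fibroblast and endothelial markers, FBLN1, a matrix protein gene, rose by 2.34, whereas COL1A1 (0.13) and PECAM1 (0.20) did not pass. Of 2 tested cancer-testis genes MAGED1 fell by 0.69 and PRAME (0.11) did not pass. Adjusted over the list alone, 2, 1 and 1 members of these lists changed, and each list was too small for a list test.

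Some of the changed genes lay in stretches of the reference order in which neighbouring genes shifted the same way. On chromosome 13, 80 of 85 tested genes from PROSER1 to CDC16 were higher on arrays labelled PSMA and 1 was lower, with a median log2 difference of 0.83. The stretch held DNAJC15, KCTD12, GPALPP1, IRS2 and COL4A1, as well as the retinoblastoma gene RB1 (0.95). On the same chromosome, 30 of 40 genes from CRYL1 to FOXO1 were lower and 7 higher (median -1.07), FRY among them. The 2 stretches overlap from PROSER1 to FOXO1, so the genes there count in both. On chromosome 17, 35 of 51 genes from CHD3 to SDF2 were lower and 5 higher (median -1.55), among them HS3ST3A1, SREBF1 and the kinase gene MAP2K4 (-2.57); the windows overshoot the edges of the lowered part. On chromosome 14, MAP4K5 to DLGAP5 (20 genes, median 0.41), with FERMT2 and ERO1A, and PCNX4 to PIGH (27 genes, median 0.54), with MTHFD1, were higher.

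There were 14 such stretches on 10 chromosomes, 8 higher and 6 lower. They held 405 genes (5.76% of those placed), 362 of the 4474 changed genes with a place (8.09%) and 114 of the 310 genes that differed by 2-fold or more (36.8%). The stretches were chosen for the size of these same differences, so a raised share inside them follows from that choice and is no separate evidence. ESM1 and PLK2 (chromosome 5), SIGLEC15 and DSG2 (18), GBX2 and COL6A3 (2), GLUL (1), EGFR and PPIA (7) and E2F8 (11) also lay in stretches that moved their way, and MTR (1) in a lower stretch although it rose. The interferon and mesenchymal lists had 0 members inside, and the epithelial list had 2 of 25. Without the genes in stretches, which was chosen after seeing the data, 196 genes differed by 2-fold or more. FOLH1 lies on chromosome 11 in the reference, outside the stretches, and the 20 tested genes around it had a median log2 difference of -0.22 (SD 0.546).

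**Figure D3:**
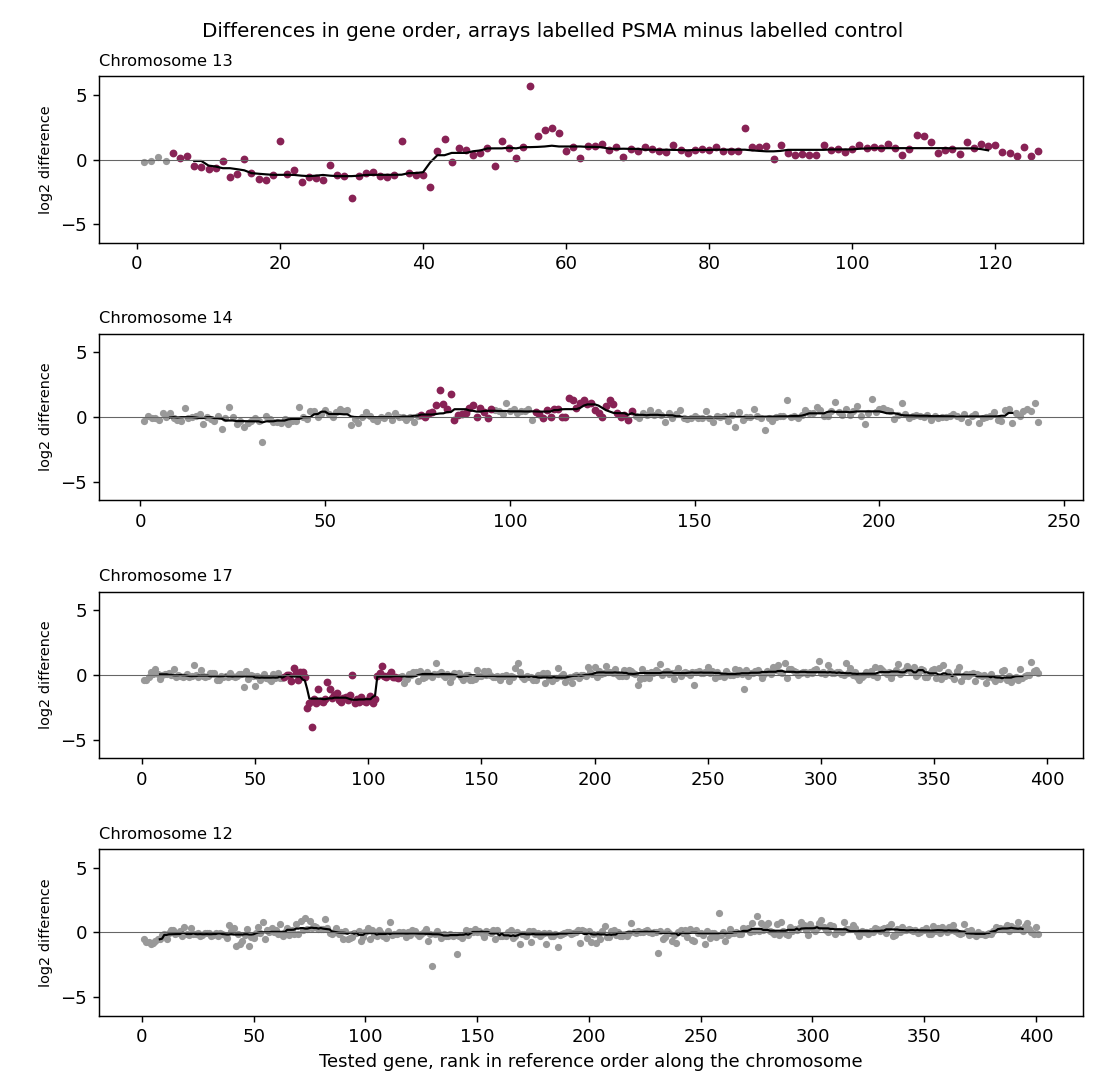
Log2 difference (arrays labelled PSMA minus arrays labelled control, n = 3 each) of each tested gene against its rank in the reference order on chromosomes 13, 14, 17 and 12, with purple points for genes inside a shifted stretch, grey points for others and a black line for the running median of 15 genes. Chromosome 13 shows a lowered stretch (median -1.07) that overlaps at its edge with a raised one (0.83). Chromosome 17 shows a lowered one (-1.55) and chromosome 12 none. The FOLH1 signal was lower on the arrays labelled PSMA.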

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

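The poly-A spike-in covariate, the removal of genes in shifted stretches and, for single genes and FOLH1, the floor on low values and the minimum fold were chosen after seeing the data; the other alternatives were not. All 110 named genes kept their call and direction in each of the 1732 values computed for them outside the minimum fold of 1.5. Apart from FOLH1, they were named because they passed in these data, so their calls were likely to hold. Under the minimum fold 62 kept their call and 48 lost it. That test uses the log2 differences of the main fit, so the direction could not change. Some genes gave no value under the stricter filter or without _x_at probe sets, nor did the neuroendocrine list, left with too few genes. Leaving out 1 array at a time gave 3999 to 4442 changed genes, 312 to 320 of them at 2-fold or more, 6078 to 6822 changed probe sets (463 to 480 at 2-fold or more), and 3 called lists each time; the adjusted p was 0.000254 to 0.000388 for the epithelial, 0.00644 to 0.0108 for the mesenchymal and 0.00644 to 0.0261 for the interferon list. The log2 difference was -5.46 to -5.05, -4.92 to -4.62 and -4.25 to -3.92 on the 3 probe sets shared by FOLH1 and FOLH1B, -2.11 to -1.93 on that of FOLH1B alone and -1.21 to -1.02 on that of FOLH1 alone. With no filter the mesenchymal list lost its call (adjusted p = 0.178); the cause was not tested. Camera with an estimated correlation called 0 lists (epithelial 0.481, mesenchymal 0.768, interferon 0.768). The correlations estimated for these lists were 0.032, 0.067 and 0.070, above the preset of 0.01. By camera, the 3 calls thus held only with the preset, and whether the higher correlation was the only cause was not tested. Fry, which asks another question, called 20. Fry turned the neuroendocrine list up (adjusted p = 0.00109); the cause was not tested. Testing against that minimum fold left 526 genes and 747 probe sets, because most differences were smaller, and kept all 5 probe sets of FOLH1 and FOLH1B. Without the genes in stretches, 4113 genes changed, 196 by 2-fold or more, fewer because those genes were removed. Camera called the 3 lists (adjusted p = 4.66e-05, 0.00444 and 0.0130). The mesenchymal and interferon lists lost 0 members and the epithelial list 2 of 25, among them DSG2, which rose. This removal was therefore little of a test for these lists. The share of higher calls stayed between 46.1% and 51.0% over the alternatives for genes. Raising low values to the 25th percentile (13) changed no gene count, since only 9 tested genes held a lower value, and lowered their folds. No paired analysis was possible because the groups share no replicate number. Signal over background limits folds against groups near the lower end of the values, such as those of FOLH1, VGLL1 and DNAJC15.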

Other observations

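Further genes with large differences, chosen after their values were seen from the 4476 that passed (63.6% of those tested), are given as single genes and were tested as no list. HPGD, an enzyme that inactivates prostaglandins, fell from 592 ± 93.9 on arrays labelled control to 93.9 ± 11.3 on arrays labelled PSMA (SD, n = 3), 6.28-fold. PTGER2, a prostaglandin E2 receptor gene, rose from 32.6 ± 2.27 to 138 ± 0.60, 4.23-fold, within a raised stretch of chromosome 14. The water channel gene AQP3 fell 5.46-fold and the adenovirus receptor gene CXADR 4.44-fold. S100P fell 3.72-fold, and S100A9 and S100A2 rose 2.59-fold and 2.35-fold. These directions follow labels that the FOLH1 signal contradicts.

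Of the tests that follow, those on FOLH1, the spike-in level and the middle 28S rRNA probe set were chosen after the result was seen. So was the correlation with 3 neighbours left out. The splits of the arrays and the correlation with 20 neighbours left out were set before their results.

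The first pattern was that the signal on the FOLH1 and FOLH1B probe sets went against the labels. Only background on the FOLH1 and FOLH1B probe sets in both groups was argued against by the brightest of them, at percentile 83.6 on arrays labelled control; it is shared by both genes, so which of them gave the signal stays open. RNA of an androgen-responsive prostate line among the cells labelled control was examined with markers of such cells, each compared with itself between the groups. The log2 difference was 0.19 for KLK2, 0.14 for KLK3, -0.0872 for ACP3, -0.02 for TRPM8 and -0.08 for TMPRSS2, all 5 below the filter. This argues only against a share of such RNA large enough to lift these dim probe sets, and a smaller share stays possible. An exchange of the labels of the 2 groups and a real difference in FOLH1 between these cell populations cannot be told apart, since both would separate the groups this way on 5 of 5 probe sets. No array was regrouped.

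The second pattern was the breadth of the change, 4476 of 7035 genes. Handling marked by the poly-A spike-in level as the whole source was argued against by 8 pairs of arrays of different groups whose levels lay no further apart than those of arrays of the same group (at most 1.15 on the log2 scale): the SD of their log2 differences over probe sets was at least 0.489, against at most 0.148 within groups. The middle 28S rRNA probe set was 2.22-fold higher on arrays labelled control with no overlap. The 5' one did not overlap either, with a smaller gap (means 5778 and 4047). RNA preparation or handling marked by the middle probe set cannot be told apart from the groups. The biological difference named by the design stays open beside it. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05: the real split alone (1 of 10) reached its count of 4476 genes, 6846 probe sets and 3 lists. The other splits reached at most 0 genes by limma (at most 96 at an unadjusted p under 0.05, against 4706 in the real split), 0 probe sets and 2 lists, and 6 of the 9 other splits called at least 1 list. Each of these other splits put arrays of both labels on both sides. Low gene counts there follow from any large difference between the labels, whatever its source.

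The third pattern was that neighbouring genes shifted together. Across genes, which are not independent replicates, the log2 difference correlated with that of flanking genes at r = 0.448 with the 3 nearest on each side left out, while 10000 shuffled orders reached at most 0.0606 (permutation p = 0.0001, the smallest they can give). Shared regulation of adjacent genes alone was examined with the 20 nearest left out. There r was 0.268, where shuffled orders reached at most 0.0604, so the shift reached past adjacent genes. Stretches of 40, 51 and 85 genes came from the same differences, so this r restates them and is no separate evidence. A hypothesis is that the 2 cell populations may differ in copy number on parts of chromosomes 13, 14, 17 and others, as separately selected sublines could; DNA was not measured here. If so, part of the difference between the groups might not come from the transfected gene, and these data hold no test that separates the 2 sources.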
